A study of Mus musculus with 6 samples.

How the data were processed

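Total RNA from 6 mouse samples was measured on Affymetrix expression arrays, 1 per sample. The samples fall into 4 groups by age and condition: 1 embryonic DR, 1 embryonic WT, 2 postnatal DR and 2 postnatal WT. Condition and age were taken from the sample titles. Replicate numbers follow the order of the samples and pair none by themselves. The 2 arrays with an extra title tag are 1 postnatal DR and 1 postnatal WT array, the 2 numbered 2, and the tag was used only as a block in an alternative fit.

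The deposited values are probe set intensities on a linear scale, 1 per probe set and array. The mean of the authors' intensity values, without the 2% lowest and 2% highest, was 150.0 on every array. The values thus share a common scale, but how they were scaled, the software, the background correction and any detection calls are not given in the sources used here. Where arrays share a mean, a sample with many abundant transcripts of another tissue can read lower for its other genes. The number of arrays limits the precision.

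Values were taken to log2(intensity + 16) with no further normalization, since the trimmed means lay within 10% of their mean. Adding 16 makes the differences of dim probe sets smaller. The 64 control probe sets were left out. Of the other 45037, those with a mean log2 at or above the 40th percentile (5.25, an intensity of 22.1) were kept, which left 27022. Gene symbols came from the platform annotation: 35890 probe sets are listed, 34958 with 1 symbol and 932 with several, and 9211 are not listed and stay unnamed here. Probe sets with several symbols were tested but not named. Of the single symbols, 34754 were found in the reference gene table of the GRCm38.p6 assembly, and 0 needed an update. The tested probe sets with 1 symbol numbered 22954 and stand for 12421 genes. Where a single value per gene was needed, the probe set with the highest mean level was used.

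Tests used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Postnatal DR against WT and the interaction of condition and age came from a fit of 4 group means with 2 residual degrees of freedom. DR against WT adjusted for age, and postnatal against embryonic adjusted for condition, came from an additive fit with 3. The embryonic pair has 1 array per group, so it is given as differences, with the number of probe sets at 2-fold or more. Its lists are given by the percentile of their median among 10000 random lists of the same size matched on mean level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

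Before the data were examined, 36 gene lists with 643 entries were fixed for cell types, brain regions, tissues next to the brain, pathways and the intramembrane proteases. Of the entries, 639 had a symbol in the reference. The 33 lists with at least 5 measured genes were tested with limma's camera, which asks whether a list's genes rank higher or lower than all others, at a preset correlation of 0.01 and again with an estimated correlation. A rule fixed at the same time chose the named genes. Per tested comparison it takes up to 12 in each direction among probe sets that passed, carry 1 symbol and lie on the same side in all matched arrays. Where fewer passed, it adds the next by p-value up to 6, as values with no claim. For the embryonic pair it takes the 10 highest and 10 lowest at or above the 60th percentile of level. It also takes up to 4 members per list and any measured protease.

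The procedure was tested on simulated arrays with 27022 probe sets, 100 of them changed 2-fold and 100 changed 4-fold. For the postnatal comparison it recovered 4% and 91% with 12 false calls. For DR against WT adjusted for age it recovered 22% and 96% with 8, for age 15% and 97% with 15, and for the interaction 0% of both sizes with 1. For DR against WT adjusted for age, a simulated list of 20 genes moved by 0.5 on the log2 scale, among 12421 genes, had a camera adjusted p of 4.90e-09 with the preset correlation and 0.198 with an estimated one, and 0 of 32 other lists were called. The simulated probe sets were drawn independently, with no array standing apart. In the real data the estimated correlation reached 0.930, for skin, muscle and bone. The simulation thus cannot show how often lists are falsely called, or changes recovered, in these data.

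The alternatives were offsets of 1 and 64, quantile normalization, median centring, no filter and a 60th percentile filter, an intensity trend, array weights and the tag as a block. Fits of the postnatal or the WT arrays alone, other fold limits, the mean of all probe sets of a gene, and each array left out in turn were also tried. The alternatives for gene lists were planned for DR against WT. Those for the age, postnatal and interaction lists, a term for sex, read from Xist, the age fit without either embryonic array, a 4-fold limit for the embryonic pair and the count of sign changes over list members were added after the data were seen.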

Results

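The study asked how lowering the expression of a polytopic protease, an enzyme that spans a membrane several times, affects the mouse brain. Total RNA was hybridised to 6 Affymetrix mouse expression arrays, each with 45101 probe sets. DR marks samples with the protease downregulated and WT marks control samples; the labels do not name the protease. There were 1 DR and 1 WT array from embryonic brain, and 2 DR and 2 WT arrays from postnatal mice. 1 DR and 1 WT postnatal array, both numbered replicate 2 here, carry a further tag in their titles whose meaning is not given. The descriptions of these 2 tagged arrays name postnatal mice but not the tissue. The labels do not say whether the arrays stand for separate animals. The 2 postnatal WT arrays differed in sex-linked genes, and so do not stand for 1 animal. For the 2 postnatal DR arrays nothing shows this, and they may stand for 1 animal. Muscle and cartilage genes differed widely between the 2, as given below, so their spread also holds a difference between the samples. The p-values measure the spread between the arrays. The trimmed mean intensity was 150.0 on every array, and the median intensity lay between 35.5 and 43.0. The number of arrays limits the precision. Levels and differences are on the log2(intensity + 16) scale, which understates the change of dim probe sets, and 27022 probe sets were tested.

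The arrays differed in sex-linked genes and in genes of muscle and cartilage. Xist, the RNA that silences an X chromosome in female cells, lay between 12 and 12.23 on the 3 DR arrays and postnatal WT replicate 2, but at 6.13 and 6.27 on the embryonic WT array and postnatal WT replicate 1. Eif2s3y, a Y-linked gene, lay at 8.21 and 7.96 on those last 2 arrays and between 4.02 and 4.35 on the others. So 4 arrays carried a female pattern and 2 a male pattern, both of them WT. Postnatal DR replicate 1 stood apart in genes of muscle and cartilage. The fast muscle myosin light chain Myl1 had an intensity of 4516 there and of at most 8.69 on the other 5 arrays. The cardiac actin Actc1 had 2321 against at most 28.0, and the skeletal actin Acta1 6451 against at most 127.6. The cartilage collagen Col2a1 had 2186 against at most 62.7. The keratins Krt18, Krt8 and Krt10 had 123.7, 54.0 and 224.0 against at most 48.2, 35.0 and 214.4. The 5' control probe set for 18S ribosomal RNA read 3982 on this array and between 105 and 1108 on the others. Over all tested probe sets, which are not independent replicates, Pearson's r of this array with the others was 0.911 to 0.949. The first principal component, with 44.4% of the variance, placed it at 76.1 against -38.7 to 14.8 for the others. The 2 tagged arrays, DR and WT, had the highest r of all pairs, 0.982.

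Of the 23 intramembrane proteases and partners listed because the target is not named, 18 had a tested gene, and none passed the test for DR against WT adjusted for age. H13, which encodes signal peptide peptidase, had the lowest mean over its probe sets, a log2 difference of -0.72. Each of its 6 tested probe sets was lower on average on the DR arrays, and within each DR and WT pair (embryonic, untagged postnatal and tagged postnatal) 5 of the 6 were lower. The brightest differed by -1.03 ± 0.37 (SE, n = 3 DR and 3 WT arrays; limma adjusted p = 1.00 over all probe sets and 0.434 adjusted over the list alone). It was at -0.57 with either embryonic array left out, at -0.63 with array weights and at -0.32 with sex as a term, and in the tagged pair it was higher on the DR array, by 0.152. The largest difference, -1.23 ± 0.35 (SE), was that of another of the 6, at -2.02 with sex as a term and -0.76 with an offset of 64. Mcts2, a gene that lies within H13 in the reference annotation, differed by -1.16 ± 0.28 (SE) with an adjusted p of 1.00. Among the other measured members, Psenen and Ncstn, both subunits of gamma-secretase, had mean differences of 0.37 and -0.37, the latter the lowest after H13. Psen2, a catalytic subunit of the same enzyme, differed by 0.04, Sppl2a by -0.28, Sppl3 by 0.18, the site-1 protease Mbtps1 by -0.08 and the mitochondrial rhomboid Parl by 0.12. With sex as a term Ncstn turned to 0.036, and at least 1 probe set each of Psen2, Sppl2a, Sppl3, Mbtps1 and Parl changed sign under an alternative. The median of the list was 0.01, with 9 members higher and 9 lower (camera adjusted p = 0.882, and 0.934 with an estimated correlation).

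**Figure D1:**
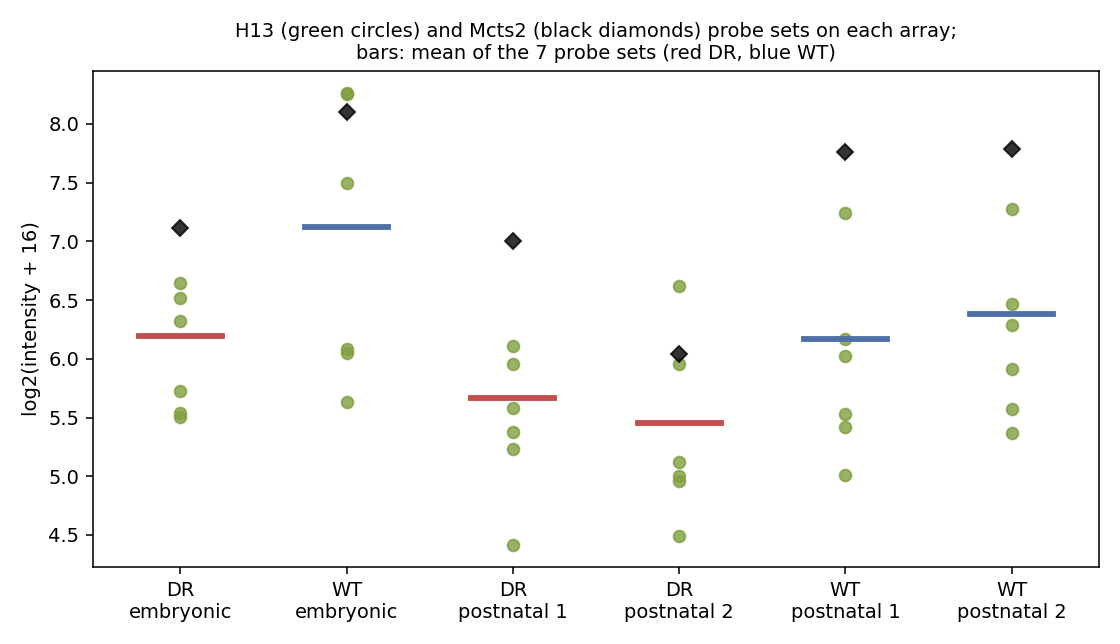
Each point is 1 probe set of H13 (6, circles) or Mcts2 (1, diamonds) on 1 array, with log2(intensity + 16) on the vertical axis, and each bar is the mean of the 7 probe sets on that array. The bars stand at 6.20 and 7.13 on the embryonic DR and WT arrays, at 5.67 and 5.45 on the postnatal DR arrays and at 6.16 and 6.38 on the postnatal WT arrays; no probe set passed the test over all probe sets.

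The comparison of all DR with all WT arrays, with age in the model, addressed what lowering the protease changed at both ages. Among genes higher on DR arrays, the smallest p-values belonged to Mfap4, a microfibril-associated glycoprotein, at 1.48 ± 0.34 (log2 difference ± SE, n = 3 DR and 3 WT arrays). Pax7, a transcription factor of dorsal midbrain and muscle progenitors, followed at 1.36 ± 0.32. Otx2, a transcription factor of forebrain, midbrain and choroid plexus, was also among them, at 0.93 ± 0.24. Actr1a differed by 1.00 ± 0.25, Rps27 by 0.96 ± 0.25 and the collagen cross-linking enzyme Lox by 0.78 ± 0.22. Among those lower on DR arrays they belonged to the circadian transcription factor Npas2 at -1.14 ± 0.23 and the RNA-binding protein gene Celf2 at -1.26 ± 0.29. Also on the lower side were Ubxn2a at -1.02 ± 0.24, Kdm5a, a histone demethylase, at -0.94 ± 0.24, Desi1 at -0.84 ± 0.20 and Mcts2, given above. Of their own 3 pairs, Pax7 and Otx2 differed most in the embryonic one, by 2.13 and 1.39. Each was lowest on the embryonic WT array, at 4.13 and 6.35. Both belong to a list of thalamus and midbrain genes that was written after some of its members had been seen high on the embryonic DR array. The rule for named genes took only those on the same side in all 3 DR and WT pairs, so this holds for each of the 12 by choice. None of them passed. With limma, 0 of 27022 probe sets had an adjusted p under 0.05, and 398 had an unadjusted p under 0.05 (101 higher and 297 lower on DR arrays) where 1351 would be met by chance. With the title tag as a block these counts were 0 and 1041, and with sex as a further term 0 and 421. In that fit the sex difference rests on postnatal WT replicate 2, the 1 female WT array. Without postnatal WT replicate 2 the adjusted count was 4. Within the embryonic pair 786 probe sets differed by 2-fold or more, within the untagged postnatal pair 1528 and within the tagged pair 219.

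Of 33 gene lists tested with camera, 12 passed an adjusted p of 0.05 in this comparison, 9 higher and 3 lower on DR arrays. Without postnatal DR replicate 1 the higher lists no longer outnumbered the lower ones. None of the 12 passed with an estimated correlation, where the adjusted p was 0.485 for each. No member of them passed over all probe sets or adjusted over the list alone, so member values are given as such. The highest list was skin, muscle and bone, with 11 of 11 measured members higher and a median of 1.66 (adjusted p = 3.48e-05). Its embryonic, untagged and tagged pair medians were -0.31, 4.94 and -0.02. Without postnatal DR replicate 1, the array with the muscle and cartilage genes, the median was -0.14 (adjusted p = 0.0469). Genes of meninges and fibroblasts followed, 13 of 15 higher with a median of 0.41 (adjusted p = 3.48e-05). Among them were the collagen Col3a1 at 0.80 ± 0.41 and the proteoglycan Lum at 1.08 ± 0.58; without that array the median was -0.04 (adjusted p = 0.872), and in the embryonic pair it was -0.078. The cerebellum list had 9 of 10 members higher and a median of 0.21 (adjusted p = 0.00279), and 0.02 (adjusted p = 0.189) without it; its embryonic pair median was -0.045. The hindbrain and spinal cord list, mostly Hox genes, was lower for 7 of 8 members with a median of -0.37 (adjusted p = 0.00278), and -0.20 (adjusted p = 0.109) without it; Lbx1 differed by -0.46 ± 0.20 and Hoxb5 by -0.70 ± 0.42. With either embryonic array left out the skin and meninges medians were 2.5 and 0.67, and without DR replicate 2 they were 2.81 and 0.64. Without WT replicate 2 the meninges median was 0.27 and the hindbrain median -0.19, and without WT replicate 1 the cerebellum median was 0.13. With sex as a term the meninges and cerebellum medians were 0.66 and 0.12, and with an offset of 64 the hindbrain median was -0.20.

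Camera also called the glycolysis, unfolded protein response, cholesterol and heat shock lists higher on DR arrays, each with an adjusted p of 0.485 with an estimated correlation. Oxidative phosphorylation and the proteasome did not pass (adjusted p = 0.108 for both). Glycolysis and hypoxia genes were higher for 15 of 17 members with a median of 0.29 (camera adjusted p = 1.41e-05; adjusted p = 0.485 with an estimated correlation). Among them were Ankrd37, a target of hypoxia signalling, at 0.98 ± 0.40, the glucose transporter Slc2a1 at 0.70 ± 0.35 and hexokinase Hk2 at 0.49 ± 0.22. The unfolded protein response and ER chaperones list had 16 of 24 members higher and a median of 0.16 (adjusted p = 0.0014). The disulfide isomerase Pdia4 was at 0.65 ± 0.26, the chaperone Hspa5 at 0.46 ± 0.21 and Xbp1 at 0.49 ± 0.25; its pair medians were 0.14, 0.06 and 0.23. All 16 measured genes of cholesterol synthesis were higher, with a median of 0.16 (adjusted p = 0.00279) and the squalene synthase gene Fdft1 at 0.53 ± 0.28, although their embryonic pair median was -0.21. Heat shock proteins had a median of 0.09 (9 of 11 higher, adjusted p = 0.0138) and an embryonic pair median of -0.055. Radial glia and neural progenitors had 0.15 (14 of 18 higher, adjusted p = 0.00343) with the Notch target Hes5 at 0.98 ± 0.41, and cell cycle genes 0.11 (23 of 28 higher, adjusted p = 0.00427), with -0.036 in the embryonic pair. Synapse genes were lower for 16 of 19 members with a median of -0.21 (adjusted p = 0.00427), with the vesicle proteins Sv2b at -0.47 ± 0.23 and Vamp2 at -0.45 ± 0.27, though none passed singly. Excitatory neuron genes were lower for 11 of 15 members with a median of -0.13 (adjusted p = 0.0277), with the vesicular glutamate transporter Slc17a7 at -0.68 ± 0.37, but their tagged pair median was 0.020. With sex as a term the heat shock, radial glia, cell cycle, synapse, excitatory neuron and cerebellum lists no longer passed (adjusted p = 0.293 to 0.917). Their medians were then 0.19, 0.16, 0.12, 0.11, -0.20 and 0.12, so the first 3 and that of excitatory neurons were no closer to 0 than without the term, while the synapse median turned. Hes5 then stood at -0.048 and Vamp2 at 0.024. In the same fit glycolysis, unfolded protein response and cholesterol genes had 0.50, 0.34 and 0.34. With quantile normalization the heat shock median was 0.041 and did not pass (adjusted p = 0.0640), and with the mean of all probe sets of a gene radial glia had 0.094 and excitatory neurons -0.21. Without postnatal DR replicate 1 the excitatory neuron list no longer passed, at -0.09 (adjusted p = 0.788), and the unfolded protein response and cholesterol medians were 0.105 and 0.096. Without postnatal WT replicate 1 the number of lists past the test was 6, and radial glia, cell cycle, synapse, excitatory neuron, cerebellum, cholesterol and heat shock genes no longer passed (adjusted p = 0.0516 to 0.339). The cell cycle and synapse medians were then 0.036 and -0.043. Without DR replicate 2 the radial glia, cell cycle, synapse, cholesterol and heat shock lists no longer passed (adjusted p = 0.0654 to 0.533), with cell cycle at 0.063 and synapse at -0.125, and excitatory neurons had -0.25. Without WT replicate 2 the hindbrain, unfolded protein response and cholesterol lists no longer passed (adjusted p = 0.0955 to 0.332). The unfolded protein response median was then 0.105, radial glia had 0.23, cell cycle 0.18 and excitatory neurons -0.19. With either embryonic array left out, cell cycle and heat shock genes both had 0.175, cholesterol 0.33 and excitatory neurons -0.25. Glycolysis and hypoxia genes passed with each array left out in turn and with the sex term, but their median was 0.144 without WT replicate 2, 0.21 without DR replicate 1 and 0.40 with either embryonic array left out. Against the other 5 arrays it stood at 0.533 on DR replicate 1, at -0.433 on WT replicate 2 and between -0.17 and 0.136 on the remaining 4.

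The protease list and 20 further lists did not pass in this comparison (camera adjusted p = 0.0508 to 0.932). Medians of the signalling and neuronal lists were 0.02 for Notch pathway, -0.03 for gamma-secretase substrates, 0.01 for newborn neurons, 0.05 for inhibitory neurons, -0.15 for striatal neurons and 0.20 for activity-regulated genes. For glia, vessels and other tissues they were -0.04 for astrocytes, -0.04 for oligodendrocytes and myelin, -0.04 for oligodendrocyte precursors, 0.06 for microglia and macrophages, 0.09 for endothelial cells and pericytes, 0.06 for choroid plexus and ependyma and -0.23 for hypothalamus and pituitary. The remaining medians were 0.08 for proteasome, -0.09 for MHC class I and interferon response, 0.09 for oxidative phosphorylation, 0.08 for ribosomal proteins, 0.05 for autophagy and lysosome, 0.05 for Wnt pathway and -0.03 for apoptosis and p53 targets. In the choroid plexus list, Otx2 alone passed when adjusted over the list alone. Lists with under 5 measured members were not tested: Alas2, the 1 measured blood cell gene, differed by 0.01 ± 0.50 (SE) and changed sign with any 1 of the 4 postnatal arrays left out, and the 4 olfactory and eye genes had a median of 0.25. The 2 sex-linked genes, which passed when adjusted over that list alone, are given above per array.

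**Figure D2:**
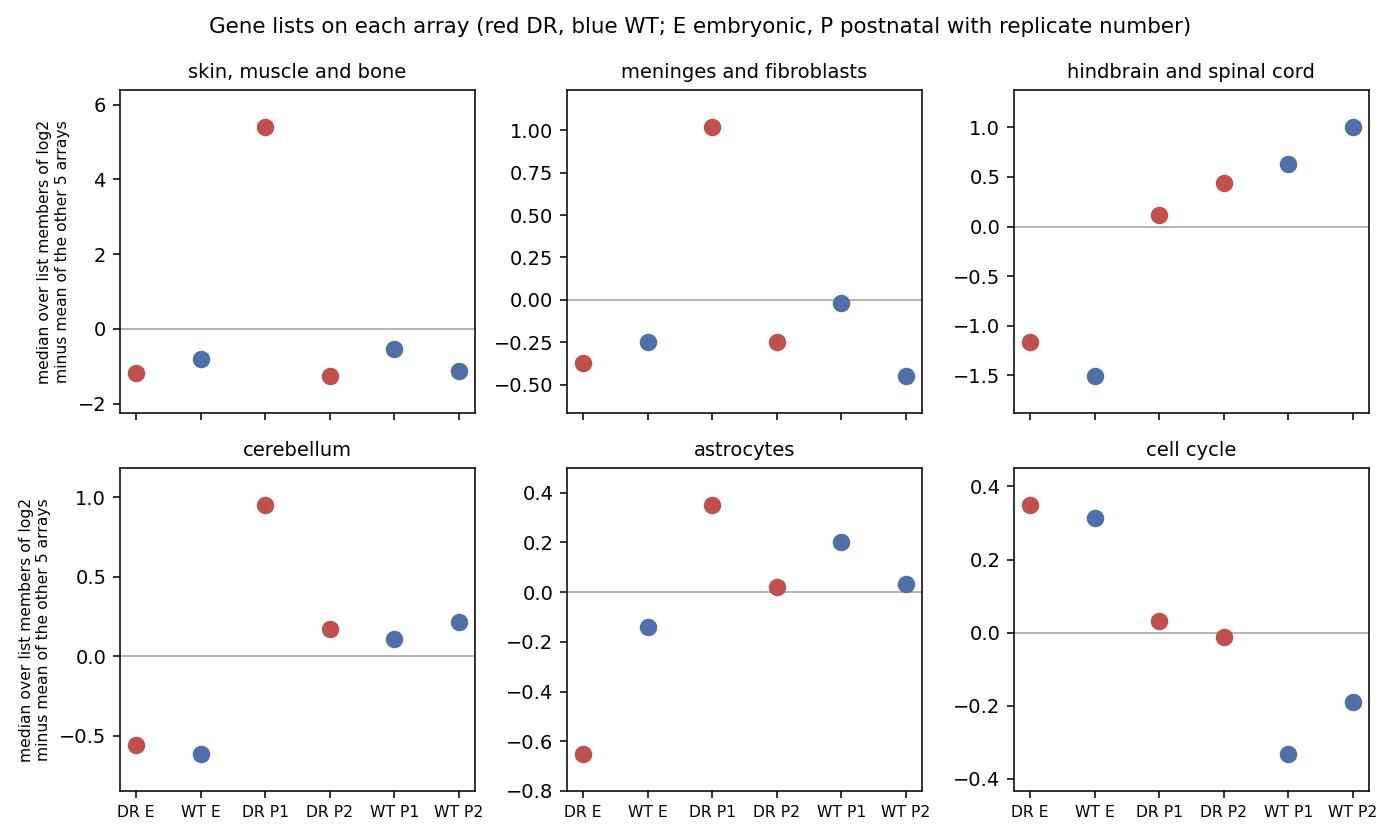
Each point is 1 array, and the vertical axis is the median over a list's measured members of their log2 level minus the mean of the other 5 arrays, with a separate scale in each panel. Postnatal DR replicate 1 lies 5.39 above the other arrays in the skin, muscle and bone list and 1.02 above them in the meninges and fibroblast list, and both embryonic arrays lie below the 4 postnatal arrays in the hindbrain and cerebellum lists.

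After birth, 2 DR arrays were compared with 2 WT arrays. The genes with the smallest p-values among those higher on both DR arrays were Depp1, a target of FoxO transcription factors, at 1.66 ± 0.30 (log2 difference ± SE, n = 2 and 2), and the matricellular gene Ccn1 at 2.21 ± 0.47. Also among them were Ankrd37 at 1.58 ± 0.35, Mfap4 at 1.54 ± 0.45, Ptdss2, a phosphatidylserine synthase, at 1.33 ± 0.38 and the transcription factor Klf4 at 1.29 ± 0.40. Those lower on both were the meiotic cohesin Rec8 at -1.44 ± 0.35, the non-coding RNA A330076H08Rik at -1.32 ± 0.36, the neuronal pentraxin Nptx1 at -1.13 ± 0.31, Tmem94 at -1.17 ± 0.32, Lztfl1 at -2.14 ± 0.60 and Npas2 at -1.11 ± 0.32. None of these 12 passed. Lztfl1 was at -1.21 without WT replicate 2, and without DR replicate 1 Mfap4 was at 0.89 and Klf4 at 0.77. With limma, 0 probe sets had an adjusted p under 0.05 and 285 an unadjusted p under 0.05 (92 higher and 193 lower), where 1351 would be met by chance. With the title tag as a block the counts were 0 and 1946. A shift shared by the 2 tagged arrays stays in the spread of the fit without the block. Between the DR replicates 3128 probe sets differed 2-fold or more and between the WT replicates 1328, against 1528 and 219 within the untagged and tagged DR and WT pairs. Leaving out 1 array gave 604 probe sets without DR replicate 2, 10 without DR replicate 1, 5 without WT replicate 2 and 2 without WT replicate 1, in fits with 1 residual degree of freedom that assume the lone array varies like the others.

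Camera called 17 of 33 lists in the postnatal comparison, 14 higher and 3 lower on DR arrays, and none with an estimated correlation. For several the untagged pair, which holds postnatal DR replicate 1, had the larger median. That pair also set a female DR array against a male WT array, while both tagged arrays carried the female pattern. No fit of the postnatal comparison held a term for sex. For skin, muscle and bone the median was 2.5 (adjusted p = 1.50e-07, and 0.621 with an estimated correlation), with untagged and tagged pair medians of 4.94 and -0.02. The median was 0.67 (adjusted p = 3.73e-07, and 0.621 with an estimated correlation) for meninges and fibroblasts, with pair medians of 1.07 and 0.16. For choroid plexus and ependyma it was 0.28 (adjusted p = 0.0235, and 0.621 with an estimated correlation), with 0.47 and -0.08. Cerebellum genes had 0.24 (adjusted p = 0.00462, and 0.621 with an estimated correlation) with 0.48 and 0.01, and ribosomal proteins 0.27 (adjusted p = 0.00118, and 0.652 with an estimated correlation) with 0.38 and 0.17. Oxidative phosphorylation genes had 0.26 (adjusted p = 0.00145, and 0.652 with an estimated correlation) with 0.49 and 0.06, and the proteasome 0.22 (adjusted p = 0.00615, and 0.626 with an estimated correlation) with 0.40 and 0.06. Of the lists that follow, all but excitatory neurons had pair medians on the same side in both pairs. Glycolysis and hypoxia genes had 0.40 (adjusted p = 4.53e-06, and 0.563 with an estimated correlation) with 0.46 and 0.29. Of them Ankrd37 passed when adjusted over the list alone while Slc2a1 differed by 1.09 ± 0.39. Cholesterol synthesis had 0.33 (adjusted p = 7.50e-06, and 0.563 with an estimated correlation) with 0.42 and 0.33. Its members included Fdft1 at 0.90 ± 0.31 and Insig1, a regulator of sterol synthesis, at 0.63 ± 0.29. Activity-regulated genes, which respond to neuronal firing, had 0.31 (adjusted p = 0.00726, and 0.563 with an estimated correlation) with 0.33 and 0.26, and included Fos at 0.97 ± 0.40 and Dusp1 at 0.96 ± 0.34. The number of lists past the test was 9 without DR replicate 1, 7 of them among the 17. Without that array, skin, muscle and bone (-0.055), meninges (-0.11), choroid plexus (-0.052), cerebellum (0.066), ribosomal proteins (-0.0012), oxidative phosphorylation (-0.05) and the proteasome (3.44e-04) did not pass (adjusted p = 0.257 to 0.97), and the median was 0.25 for glycolysis. Without WT replicate 1, choroid plexus (0.21), cerebellum (0.15) and the proteasome (0.22) did not pass (adjusted p = 0.0744 to 0.287), and the median was 0.40 for ribosomal proteins. Without DR replicate 2, choroid plexus (0.44) and activity-regulated genes (0.47) did not pass (adjusted p = 0.0668 to 0.0691), and the median was 5.20 for skin, muscle and bone, 0.52 for ribosomal proteins, 0.53 for oxidative phosphorylation, 0.39 for the proteasome and 0.69 for glycolysis. Without WT replicate 2, choroid plexus (0.18), ribosomal proteins (0.10), oxidative phosphorylation (0.14), the proteasome (0.18) and activity-regulated genes (0.20) did not pass (adjusted p = 0.0677 to 0.345), and the median was 0.36 for cerebellum and 0.19 for glycolysis. After quantile normalization ribosomal proteins (0.047), oxidative phosphorylation (0.088) and the proteasome (0.10) did not pass (adjusted p = 0.678 to 0.764).

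The unfolded protein response list had a median of 0.14 (adjusted p = 0.00925, and 0.621 with an estimated correlation), with pair medians of 0.06 and 0.23; Creld2 differed by 0.70 ± 0.30 and Hspa5 by 0.62 ± 0.29. Heat shock proteins had 0.18 (adjusted p = 0.00584, and 0.563 with an estimated correlation) with 0.27 and 0.09, and cell cycle genes 0.18 (adjusted p = 0.00447, and 0.563 with an estimated correlation) with 0.18 and 0.20. Radial glia had 0.15 (adjusted p = 0.017, and 0.563 with an estimated correlation) with 0.20 and 0.12. On the lower side, all 8 hindbrain and spinal cord genes were lower, with a median of -0.43 (adjusted p = 9.27e-04, and 0.621 with an estimated correlation) and pair medians of -0.44 and -0.43. Hoxb5 was at -1.05 ± 0.50 and Hoxa3 at -0.54 ± 0.29. Synapse genes had -0.18 (adjusted p = 0.00939, and 0.621 with an estimated correlation) with -0.33 and -0.02. Excitatory neuron genes had -0.25 (adjusted p = 0.0249, and 0.621 with an estimated correlation) with -0.39 and 0.02. The other 16 tested lists did not pass, among them the Notch pathway at 0.02, gamma-secretase substrates at -0.09 and the intramembrane proteases at -0.02. Without postnatal DR replicate 1, the unfolded protein response (0.11), hindbrain (-0.24) and excitatory neurons (-0.036) did not pass (adjusted p = 0.0739 to 0.721), and the median was 0.082 for radial glia and -0.28 for synapse. Without WT replicate 1, cell cycle (0.13), radial glia (0.18), synapse (0.02) and excitatory neurons (-0.17) did not pass (adjusted p = 0.27 to 0.646), and the median was 0.30 for the unfolded protein response. Without DR replicate 2, the unfolded protein response (0.23), cell cycle (0.11), radial glia (0.30) and synapse (-0.085) did not pass (adjusted p = 0.148 to 0.766). Without WT replicate 2, the unfolded protein response (0.092) and hindbrain (-0.25) did not pass (adjusted p = 0.197 to 0.614), and the median was 0.31 for cell cycle and -0.47 for synapse. After quantile normalization the unfolded protein response (0.14), heat shock (0.09) and radial glia (0.17) did not pass (adjusted p = 0.0691 to 0.075). With an offset of 64 the median was -0.26 for hindbrain. With the mean of all probe sets of a gene the median was 0.06 for the unfolded protein response, 0.091 for radial glia and -0.35 for synapse.

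In embryonic brain, 1 DR array was compared with 1 WT array, so the differences have no replicate check and no test. Apart from Xist, which follows sex and was 64.7-fold higher on the DR array, the highest genes among brighter probe sets included the transcription factors Tfap2b (3.30 on the log2 scale), Tcf7l2 (2.86), Shox2 (2.73) and Ebf3 (2.54). The first 3 belong to a list of thalamus and midbrain genes, written after some of its members had been seen high, of which 20 of 21 were higher with a median of 1.66. The long non-coding RNA Rmst was at 2.99. Prdx2, a peroxiredoxin, was higher by 2.52, the microtubule protein Map2 by 2.43, the actin-related Actr3 by 2.40 and the GABA receptor subunit Gabra2 by 2.40. The lowest were Minar2 at -3.10, the cyclase-associated protein Cap1 at -2.86 and the potassium channel Kcnq5 at -2.79. They were followed by the polyadenylation factor Nudt21 at -2.44, the splicing factor Rbm39 at -2.11 and H13 at -1.93, with 4632415L05Rik, Zfp704, Uri1 and Akap9 between -1.93 and -1.79. In all, 567 probe sets were 2-fold or more higher and 219 lower on the DR array, and 32 and 12 at 4-fold. With the spread taken from the postnatal replicates, limma gave 0 probe sets at an adjusted p under 0.05 and 440 at an unadjusted p under 0.05. Across probe sets, which are not independent, the embryonic differences had a Pearson r of -0.195 (Spearman's rho -0.208) with those of the untagged postnatal pair and 0.0121 (rho -0.00233) with those of the tagged pair.

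Lists were placed among 10000 random lists of the same size and mean level, as a description of these 2 arrays. Astrocyte genes had a median of -0.38, below all random lists (13 of 15 lower, Gfap -0.79 and Apoe -0.70). Microglia and macrophage genes had -0.28 (percentile 0.26, the fractalkine receptor Cx3cr1 -1.11), ribosomal proteins -0.28 (percentile 0.24, 17 of 18 lower) and cholesterol synthesis -0.21 (percentile 0.3). Choroid plexus and ependyma had -0.25 (percentile 1.41), myelin -0.26 (percentile 1.55) and synapse genes -0.16 (percentile 1.7). Skin, muscle and bone genes had -0.31 (percentile 0.47). At the other end, the unfolded protein response list had 0.14 (percentile 99.9, Pdia4 1.19) and the Wnt pathway 0.23 (percentile 99.9, 8 of 15 higher, with Tcf7l2 2.86, Sp5 1.25 and Lef1 0.78). Tcf7l2 also belongs to the thalamus and midbrain genes, of which 20 of 21 were higher with a median of 1.66. Gamma-secretase substrates had 0.09 (percentile 98.7, Cdh2 0.92 and App 0.35) and glycolysis and hypoxia 0.08 (percentile 98.5). The Notch pathway had a median of -0.0096 (percentile 60.4, 9 of 20 higher and 11 lower), with Hes5 1.25 and Hes1 0.66. The 2 arrays also differed in sex-linked genes, the DR array carrying the female pattern.

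Postnatal and embryonic arrays were compared with condition in the model, 4 against 2 arrays. The homeobox gene En2, expressed at the midbrain and hindbrain boundary and in cerebellum, was higher on postnatal arrays by 2.55 ± 0.24 and Lamp5, a membrane protein of neurons, by 2.55 ± 0.23 (log2 difference ± SE, limma adjusted p = 0.0391 for both). Each was higher on all 4 postnatal arrays than on both embryonic ones, which the rule for named genes required within each condition. On the embryonic DR and WT arrays En2 lay at 4.96 and 4.46 and Lamp5 at 4.46 and 5.12, below the filter level of 5.25. Whether the samples of both ages held the same brain regions was not tested, so region cannot be told apart from age here. Another 2 probe sets, which are not named in the annotation used and were chosen after their values were seen, were higher by 3.00 ± 0.25 and 2.74 ± 0.25 (SE, limma adjusted p = 0.0391 for both). On the embryonic DR and WT arrays the first lay at 4.545 and 4.842 and the second at 4.962 and 5.611. These 2 with En2 and Lamp5 were the 4 probe sets that passed, all higher after birth. With limma, 1920 had an unadjusted p under 0.05 (869 higher and 1051 lower). Next by p-value, without passing, were Hoxa5 at 3.12 ± 0.33, Hoxb3 at 2.45 ± 0.31, Skor1 at 2.37 ± 0.29, Sncg at 2.04 ± 0.26, Car8 at 1.80 ± 0.24 and Pla2g7 at 1.69 ± 0.22. On the lower side were Eomes, a transcription factor of intermediate progenitors, at -1.12 ± 0.21 and the host gene of a neuronal microRNA, Mir124a-1hg, at -2.77 ± 0.52. Also on that side were the signalling adaptor gene Ywhaz at -1.42 ± 0.24, Hspa8 at -1.33 ± 0.25, Thap2 at -1.34 ± 0.26 and Ccdc25 at -1.27 ± 0.23. The adjusted count was 0 with the title tag as a block or with sex as a term (4848 and 1597 unadjusted). It was 0 with either embryonic array left out and without postnatal WT replicate 1, DR replicate 2 or WT replicate 2, but 12 without DR replicate 1. In the WT arrays alone, 2 against 1, it was 332.

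Of the 33 lists, 11 passed with camera, 8 higher and 3 lower after birth, and none with an estimated correlation. This split by direction changed with either embryonic array left out. All 8 hindbrain and spinal cord genes were higher, with a median of 1.47 (adjusted p = 4.79e-19, and 0.269 with an estimated correlation). All 8 passed when adjusted over the list alone, such as Hoxb5 at 2.78 ± 0.45, Hoxb3 at 2.45 ± 0.31 and Hoxc4 at 2.20 ± 0.35. Cerebellum genes were higher for 10 of 10 members with a median of 0.76 (adjusted p = 4.81e-11, and 0.284 with an estimated correlation). Of them 5 passed when adjusted over the list alone, including the Purkinje cell gene Pcp2 at 2.35 ± 0.32 and Car8. Whether the embryonic and postnatal samples held the same share of hindbrain and cerebellum was not tested, so for both lists region cannot be told apart from age. Astrocyte genes had 0.53 (adjusted p = 9.50e-07, and 0.284 with an estimated correlation), 14 of 15 higher. The water channel Aqp4 at 1.45 ± 0.24 passed over the list alone, and Apoe was at 1.10 ± 0.41. Choroid plexus and ependyma had 0.23 (adjusted p = 0.00152, and 0.545 with an estimated correlation), with Otx2 at 1.01 ± 0.25 past it over the list alone (0.66 without the embryonic WT array). Oligodendrocyte genes had 0.31 (adjusted p = 0.031, and 0.58 with an estimated correlation) and their precursors 0.23 (adjusted p = 0.0245, and 0.413 with an estimated correlation). Meninges and fibroblasts had 0.39 (adjusted p = 0.00357, and 0.601 with an estimated correlation) and skin, muscle and bone 1.25 (adjusted p = 0.0174, and 0.601 with an estimated correlation). Without postnatal DR replicate 1 these last 4 lists no longer passed: myelin had 0.19 (adjusted p = 0.215), precursors 0.17 (adjusted p = 0.086), meninges 0.08 (adjusted p = 0.216) and skin, muscle and bone -0.03 (adjusted p = 0.905). Without the embryonic DR array myelin had -0.014 (adjusted p = 0.428), meninges -0.091 (adjusted p = 0.637), skin, muscle and bone -0.013 (adjusted p = 0.855) and choroid plexus 0.048 (adjusted p = 0.205), and the astrocyte median was 0.298 (adjusted p = 0.00303). In the fit without the embryonic WT array meninges had 0.77, skin, muscle and bone 2.87 and choroid plexus 0.52. The meninges and skin medians were 0.625 and 2.28 without postnatal DR replicate 2, and 0.72 and 2.74 with the title tag as a block. With an offset of 64 the hindbrain median was 0.63, and myelin, at 0.145, did not pass (adjusted p = 0.0708). The number of lists past the test was 7 without postnatal DR replicate 1 and 7 without WT replicate 2.

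Cell cycle genes were lower after birth for 26 of 28 members, with a median of -0.41 (adjusted p = 6.86e-06, and 0.269 with an estimated correlation). They included cyclin A, Ccna2, at -0.77 ± 0.24 and Ccnd2 at -0.76 ± 0.25. Inhibitory neuron genes had -0.41 (adjusted p = 0.031, and 0.413 with an estimated correlation). Dlx1, a transcription factor of interneuron progenitors, passed over the list alone at -0.99 ± 0.23, and Lhx6 was at -1.09 ± 0.32. Cholesterol synthesis had -0.31 (adjusted p = 0.0342, and 0.601 with an estimated correlation), 14 of 16 lower. Its median was -0.57 without the embryonic DR array, -0.17 without WT replicate 2 or with sex as a term, and -0.11 with the title tag as a block. Without the embryonic WT array it was -0.042 (adjusted p = 0.819), and inhibitory neurons and oligodendrocyte precursors no longer passed (adjusted p = 0.0753 for both). Without postnatal WT replicate 1 cholesterol genes did not pass (adjusted p = 0.0562). Without WT replicate 2 these 3 lists and myelin did not pass (adjusted p = 0.0506 to 0.0980), nor did they with sex as a term. With the title tag as a block the inhibitory neuron, oligodendrocyte precursor and cholesterol lists no longer passed (adjusted p = 0.160, 0.0700 and 0.130). Single members of lists that did not pass also met the test when adjusted over their list alone: Eomes and Neurog2 (-1.59 ± 0.33) among newborn neuron genes and Vamp1 (1.32 ± 0.27) among synapse genes. So did Fos (1.73 ± 0.38) among activity-regulated genes, and Hspa1b (1.51 ± 0.32) and Hspa1a (1.03 ± 0.22) among heat shock genes. Alas2 (-1.36 ± 0.53), the single blood cell gene, had an unadjusted limma p under 0.05. Its list of 1 gene leaves nothing to adjust and was not tested. Fos was at 1.11 without the embryonic DR array and Alas2 at -0.033 without the embryonic WT array. The Notch pathway had a median of -0.11 and the intramembrane proteases -0.11, neither past the test.

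The interaction asked whether the difference between DR and WT was itself different after birth and before it, with the single embryonic arrays assumed to vary like the postnatal ones. No probe set passed with limma (0 adjusted, and 465 at an unadjusted p under 0.05, 71 higher and 394 lower). The most negative list member was Tcf7l2, a Wnt effector, at -2.83 ± 0.52 (SE), which passed when adjusted over the list alone. Alas2, the 1 measured blood cell gene, was at 2.66 ± 0.56 with an unadjusted limma p under 0.05, since a list of 1 gene leaves nothing to adjust. Tcf7l2 is one of the thalamus and midbrain genes that were higher on the embryonic DR array, there by 2.86. Its level was 6.44 on the embryonic WT array and between 9.30 and 10.15 on the other 5 arrays. Camera called 12 of 33 lists, 10 higher and 2 lower, and none with an estimated correlation (adjusted p = 0.742 for each). The postnatal minus embryonic difference of DR against WT had a median of 0.53 (adjusted p = 5.06e-05) for cholesterol synthesis, and 0.52 (adjusted p = 4.77e-05) for ribosomal proteins. It was 0.46 (adjusted p = 1.78e-04) for oxidative phosphorylation, 0.36 (adjusted p = 0.00376) for the proteasome and 0.48 (adjusted p = 6.90e-04) for microglia and macrophages, with Cx3cr1 at 1.00 ± 0.51. It was 0.77 (adjusted p = 3.35e-04) for meninges and fibroblasts and 2.88 (adjusted p = 1.78e-04) for skin, muscle and bone. Glycolysis and hypoxia had 0.24 (adjusted p = 0.0234), choroid plexus and ependyma 0.49 (adjusted p = 0.0428) and activity-regulated genes 0.32 (adjusted p = 0.0428). Hindbrain and spinal cord genes had -0.53 (adjusted p = 0.0428) and the Wnt list -0.03 (adjusted p = 0.0428). Leaving out 1 postnatal array gave between 1 and 416 probe sets, the most without DR replicate 2 and 21 without DR replicate 1. For 10 of the 12 lists postnatal DR replicate 1 was the highest array. Its median over members, relative to the mean of the other 5 arrays, was 5.39 for skin, muscle and bone, 1.02 for meninges, 0.67 for microglia, 0.572 for activity-regulated genes, 0.536 for oxidative phosphorylation and 0.533 for glycolysis. It was 0.513 for choroid plexus, 0.439 for ribosomal proteins, 0.333 for the proteasome and 0.205 for Wnt. Cholesterol genes were highest on the embryonic WT array, at 0.352, with 0.146 on both the embryonic DR array and postnatal DR replicate 1, 0.111 on DR replicate 2, and -0.249 and -0.256 on the postnatal WT arrays. Hindbrain genes were lower on postnatal DR replicate 1, at 0.116, than on the other 3 postnatal arrays, at 0.44 to 0.999, and lay at -1.16 and -1.50 on the embryonic arrays. Without postnatal DR replicate 1, 4 lists passed, 3 of them among the 12: cholesterol, ribosomal protein and Wnt genes. In that fit skin, muscle and bone (-0.055), meninges (-0.041), microglia (0.22), choroid plexus (0.073), oxidative phosphorylation (0.092), the proteasome (0.15), glycolysis (0.14), activity-regulated genes (0.15) and hindbrain (-0.29) did not pass (adjusted p = 0.0619 to 0.903), and the median was 0.28 for ribosomal proteins and -0.37 for Wnt. Without WT replicate 1, choroid plexus (0.40) and Wnt (0.056) did not pass (adjusted p = 0.227 to 0.306), and the median was 0.36 for glycolysis. Without DR replicate 2, choroid plexus (0.58), glycolysis (0.51), activity-regulated genes (0.34), hindbrain (-0.55) and Wnt (-0.22) did not pass (adjusted p = 0.068 to 0.342), and the median was 5.81 for skin, muscle and bone, 0.85 for microglia and 0.75 for oxidative phosphorylation. Without WT replicate 2, glycolysis (0.12), activity-regulated genes (0.13) and hindbrain (-0.33) did not pass (adjusted p = 0.0733 to 0.383), and the median was -0.10 for Wnt. After quantile normalization choroid plexus (0.41), oxidative phosphorylation (0.12), the proteasome (0.19), ribosomal proteins (0.013), glycolysis (0.16), activity-regulated genes (0.40), hindbrain (-0.47) and Wnt (-0.055) did not pass (adjusted p = 0.058 to 0.839). With an offset of 64 choroid plexus (0.26), activity-regulated genes (0.25), hindbrain (-0.23) and Wnt (-0.021) did not pass (adjusted p = 0.0544 to 0.0675), and the median was 0.31 for microglia. With the mean of all probe sets of a gene glycolysis (0.24) and activity-regulated genes (0.34) did not pass (adjusted p = 0.0511 to 0.0573), and the median was -0.27 for Wnt. With the title tag as a block Wnt (-0.032) did not pass (adjusted p = 0.0768). Apart from the fit with an estimated correlation, cholesterol genes passed under each of these alternatives.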

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

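The test of the interaction was planned, while the alternatives for the interaction lists, the screen of control probe sets, the further tissue lists and the tests of the muscle and cartilage pattern were chosen after results had been seen.

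The difference between DR and WT differed between ages for 12 lists by camera with a preset correlation, and for 0 with an estimated correlation (adjusted p = 0.742 for each). The postnatal minus embryonic value had a median of 2.88 for skin, muscle and bone, 0.77 for meninges and fibroblasts, 0.53 for cholesterol synthesis and 0.52 for ribosomal proteins. It was 0.49 for choroid plexus and ependyma, 0.48 for microglia and macrophages, 0.46 for oxidative phosphorylation and 0.36 for the proteasome. Activity-regulated genes had 0.32 and glycolysis and hypoxia 0.24. On the lower side, hindbrain and spinal cord had -0.53 and the Wnt list -0.032. Without postnatal DR replicate 1, 4 lists passed, 3 of them among the 12. The embryonic side of each rests on 1 DR and 1 WT array, which also differ in sex-linked genes. Of 32 control probe sets with a mean intensity of 64 or more, 1 was at least 2-fold higher on the highest DR than on the highest WT array: the 5' probe set for 18S ribosomal RNA, at 3.59-fold, on postnatal DR replicate 1.

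On postnatal DR replicate 1, 14 of 20 genes of a further skeletal muscle list and 8 of 12 of a cartilage list lay over 2 log2 units above the other 5 arrays on the log2(intensity + 16) scale, which makes differences of dim probe sets smaller. The myosin light chain Mylpf had an intensity of 2955, the highest of its list, against at most 27.3 on the others. The troponins Tnnc2 and Tnni2 had 2116 and 1693 against at most 15.4 and 16.4. Among the cartilage genes, Col9a1 had 1823 against at most 70.4, Matn1 729 against at most 21.1 and Cnmd 502 against at most 14.3. The brightest of 16 epidermis genes, Krt1, was at 228 there and at most at 216 on the others. Of the muscle, cartilage and epidermis genes, 11, 5 and 5 reached the filter intensity of 22.1 on at least 1 of the other arrays, and 0, 0 and 3 are also in the lists fixed beforehand.

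Skin, muscle and bone genes stood 5.39 above the other arrays on postnatal DR replicate 1. The tables argue against epidermis, with 0 of 16 genes (0%) over 2 log2 units above the other arrays, against the scaling of that array, with a distance of 5.32 after quantile normalization, and against an effect of DR in all postnatal DR samples, with a median of -0.021 for DR replicate 2 minus WT replicate 2. Transcripts of skeletal muscle and cartilage were high there, with list medians of 2.74 and 2.29 above the other arrays, against 0.26 for epidermis. Their shares over 2 log2 units, 70.0% and 66.7%, lay between the bounds of 50% and 80%, which were set after results had been seen. Those bounds thus do not decide whether these tissues were in that sample, and both stay open as candidate sources. The offset of 16 also held dim members under 2 log2 units. Mybpc2, at an intensity of 44.3 there and of at most 2.29 on the other arrays, differed by 1.79. An effect of DR in 1 sample was not tested. A first version used the fixed list, where 8 of 11 members (72.7%) lay over 2 log2 units and the outcome was also open. It was replaced by the 3 further lists with the same bounds after that outcome had been seen.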

How the results depend on the processing

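The sex term, the 4-fold limit, the age count without an embryonic array, all alternatives for the age, postnatal and interaction lists and the count of sign changes over list members were chosen after the data were seen, and the others were planned. In fits with the sex term, postnatal WT replicate 2 is the 1 female WT array and alone sets the sex difference. With 1 array left out of a pair, the lone array is assumed to vary like the others. Where a value moved, the cause was not tested unless it is stated.

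For DR against WT adjusted for age, limma gave 0 probe sets under each setting that left out no single array and 0 to 4 with 1 array left out. The postnatal count was 0 under each such setting and 2 to 604 with 1 array left out, and the interaction count 0 and 1 to 416. At an unadjusted p under 0.05 the counts were 398, 285 and 465. The age count of 4 became 8 with log2(value + 1), and 0 with log2(value + 64), with no filter, with an intensity trend, and with the sex term. It was 332 with WT arrays only (304 higher and 28 lower) and 0 to 12 with 1 array left out. The embryonic count of 786 became 1661 with log2(value + 1) (1025 higher and 636 lower), 201 with log2(value + 64) and 476 with the 60th percentile filter, which tests fewer probe sets. It was 3310 at 1.5-fold and 44 at 4-fold, and 0 by limma with the spread pooled from the postnatal replicates (440 unadjusted).

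With the title tag as a replicate block, the age count was 0 (4848 unadjusted), and the counts for DR against WT stayed at 0, adjusted for age (1041 unadjusted) and after birth (1946 unadjusted). The replicate numbers follow the order of the samples and pair none by themselves, but the 2 tagged arrays are the 2 numbered 2, so this is also the block by replicate number. Of the called lists of the postnatal comparison none lost its call under this block, and of those of the interaction the Wnt list did (adjusted p = 0.0768).

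Of the gene lists, 12 passed for DR against WT, 0 with an estimated correlation and 6 to 17 with 1 array left out. For age, 11 passed, 0 with an estimated correlation and 7 to 16 with 1 array left out, and 7 with the sex term. For the postnatal comparison 17 passed, 0 with an estimated correlation and 9 to 11 with 1 array left out. For the interaction 12 passed (10 higher and 2 lower), 0 with an estimated correlation, 4 after quantile normalization (4 higher and 0 lower) and 4 to 12 with 1 array left out. After birth the skin, muscle and bone list ranged from -0.055 to 5.20 and oxidative phosphorylation from -0.050 to 0.525, both lowest without postnatal DR replicate 1, where the direction of their camera test turned. The skin, muscle and bone list ranged from -0.14 to 2.81 for DR against WT with 1 array left out, and was -0.14 without postnatal DR replicate 1, whose muscle and cartilage genes it holds. The cholesterol list ranged from -0.57 to -0.042 for age, and without the embryonic WT array, at -0.042, the direction of its camera test turned. For DR against WT medians also changed sign for the synapse list with the sex term (0.11) and for meninges without postnatal DR replicate 1 (-0.036). Without that array they also did so after birth for meninges (-0.11), choroid plexus (-0.052) and ribosomal proteins (-0.0012), and in the interaction for meninges (-0.041) and skin, muscle and bone (-0.055). Without postnatal WT replicate 1 the synapse list did so after birth (0.020) and the Wnt list in the interaction (0.056). For age they did so for myelin (-0.014), meninges (-0.091) and skin, muscle and bone (-0.013) without the embryonic DR array, and for the last (-0.033) without postnatal DR replicate 1. Under the alternatives run, 0 of the genes chosen by p-value or size and of the H13 probe sets for DR against WT adjusted for age changed sign. The rule took genes of the tested comparisons only where they lay on the same side in all matched arrays, so leaving out an array could not turn them. Those of the embryonic pair were chosen as its largest differences. For these chosen genes the count of 0 is thus no measure of stability. Among the list members and protease probe sets a sign change under at least 1 alternative was met by 43 of 163 for DR against WT adjusted for age, 37 of 164 after birth, 32 of 165 for age, 6 of 138 for the interaction and 6 of 164 in the embryonic pair. With 1 array left out, 133, 136, 112 and 88 of the values of the first 4 moved by over 1.5 times or changed sign. Signal over background limits the dim probe sets, and it is not known here since no detection calls were used.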

Other observations

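The tests of the thalamus and midbrain genes and of H13 and Mcts2 were chosen after the patterns were seen, and the counts over other splits of the arrays were planned.

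Muscle genes on postnatal DR replicate 1 differed in how far they stood out. Mybpc1, a thick filament protein, had an intensity of 454 there and of at most 34.6 on the other 5 arrays, and Eno3, the muscle enolase, 858 against at most 66.9. The myogenic transcription factor Myog had 34.9 against at most 9.44, and the calcium release channel Ryr1 71.5 against at most 68.9. The difference between the untagged and the tagged array was compared between DR and WT samples. Across 27022 probe sets, which are not independent replicates, the difference between the DR replicates and that between the WT replicates had a Pearson r of 0.534 (Spearman's rho 0.543). The DR and WT differences of the untagged and of the tagged pair had an r of 0.138 (rho 0.164).

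In the embryonic pair, 20 of 21 measured genes of thalamus and midbrain were higher on the DR array, with a median of 1.66, but the list was written after some of its members had been seen high, so this is partly circular. Against each gene's mean over all arrays, the list's median was -1.51 on the embryonic WT array and 0.005 on the embryonic DR one. It lay between 0.21 and 0.62 on the postnatal arrays, so the embryonic WT array stood lowest. A different share of brain regions in the 2 samples may account for the difference and stays open. The telencephalon list lay at -0.11 and at percentile 15.1 of random lists, between the bounds of 2.5 and 50. A small added share of other regions would lower that list only a little, so its value cannot decide this. Sex stays open, at 0.051 for the female minus the male postnatal WT array, since there is 1 array of each. The DR condition stays open too, at -0.088 in the lower of the postnatal pairs, since that sets no limit on an effect in embryos. A first version of the sex test had excluded sex, and its rule was changed because 1 array per sex cannot do so.

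The mean of the H13 and Mcts2 probe sets was lower on each DR array than on each WT array of its age, and a hypothesis found and tested on the same data is that the DR condition may lower them. The tables argue against tissue on postnatal DR replicate 1, with a mean difference of -0.87 without that array and -0.78 ± 0.12 (SE) with it. Chance among many genes stays open, since 1 of 12 arrangements of DR and WT within age, the real one, gave a mean moderated t as low for the lowest of the 18 protease genes, an exact one-sided permutation p of 0.0833 (0.125 over the 8 that exchange only within the tagged and untagged pairs), the smallest each can give. Sex stays open, at -0.87 ± 0.19 (SE, 95% interval -1.71 to -0.028) with sex in the model, since 1 female WT array stands behind that value. The DR condition stays open too. Its exact two-sided permutation p was 0.167 over the 12 arrangements and 0.25 over the 8, again the smallest each can give. Both genes were chosen as low on DR arrays, so the real arrangement was likely to be among the most extreme. The 2 permutation p-values for the condition, the SEs and the interval take no account of that choice. A first test of sex, by sign flips over the probe sets of the tagged pair, had excluded sex and was replaced by the model with sex. A first reading of that model had excluded it too and was withdrawn because of the 1 female WT array. A first test of the condition, a rank among nested gene pairs, had favoured it. A first test of chance, a rank among genes, had argued against it. Both were dropped as void because the genes were chosen for the pattern.

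The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For probe sets past the threshold, the real split gave 0, so all 10 give as many and the count decides nothing. The highest other gave 127. With age in the model, that split, which has both embryonic arrays on 1 side, compares postnatal DR replicate 1 alone with the other 3 postnatal arrays. The structure of the samples it points to is thus this array standing apart, and the splits that set each other postnatal array alone gave 0, 1 and 0. For gene lists, the real split gave 12 and the highest other 14, and 2 of the 10 splits, the real one included, gave 12 or more.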
